A study of Ipomoea batatas with 28 samples.

How the data were processed

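Messenger RNA was profiled in roots of wild type sweet potato (Ipomoea batatas), a hexaploid crop whose storage roots form by thickening of roots that begin as thin fibrous roots. Per the labels, RNA came from the middle part of the root at 7 stages, each with a stated root diameter, and 4 biological replicates were sequenced per stage, which gave 28 libraries. Per the labels' protocols, total RNA was isolated with the RNeasy Mini Kit and libraries were made with the Illumina TruSeq RNA kit. The labels name S4 (1.5 mm) and S8 (2 mm) as fibrous roots, S10 (3.5 mm) and S12 (5 mm) as pencil roots, and S14 (10 mm), S16 (15 mm) and S20 (25 mm) as storage roots. The 3 root classes therefore held 8, 8 and 12 libraries.

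The authors deposited a single table of TPM values, a transcript abundance scaled to a fixed total per library, with 1 column per library and 99697 rows. TPM divides each gene's read number by its length and scales each library to the same total, so a value is a share of the library and not an amount per cell. TopHat2 2.0.0 and RSEM 1.3.1 were named, per the submitters' processing notes, and the role of each tool, the genome build and the annotation were not given in the sources used here. Every column summed to the same total within rounding. TPM keeps no depth, so the number of reads behind each value was unknown and no counting interval was computed. The precision of each value was therefore judged only from the spread between replicates.

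The rows carried IDs of 2 kinds, 75502 with a G and TU number and 24195 with the prefix MSTRG. Of these IDs, 0 matched the reference table used here, which held 175826 rows, so no ID was given a gene name. The gene lists fixed beforehand, the test of each list and the values of IbNAC083, the gene in the title of the series, are not reported here for that reason. Each row is called an ID below, since 17095 of 49007 distinct G numbers had more than 1 row and a row need not be a whole gene. Where near-identical copies exist, as they do in a hexaploid, the division of reads between IDs is uncertain.

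IDs with at least 1 TPM in at least 4 libraries were tested (75757 IDs), and 3459 IDs were at 0 in every library. Values were analysed as log2(TPM + 1), and every fold change is on that scale, which understates the change of low IDs. limma 3.58.1 in R 4.3.3 was fitted to the 7 stage means over all 28 libraries, with a trended prior. Neighbouring stages were contrasted, as were the root classes, each taken as the unweighted mean of its stage means. An ID was called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 fold change of at least 1 in size. A limma F test over the stages and a limma slope on log2 diameter used the adjusted p alone. The spread between replicates was measured as the distance of each library from its stage mean, divided by the square root of the number of IDs. Each stage was compared with the other libraries by a two-sided exact permutation test over 20475 choices of 4 libraries. Exact means here that every choice was counted. The distances of a stage share its mean and are not independent, so the p-values of the spread are approximate. A simplified network index, after the method named in the title of the series, multiplied the mean SD of IDs with at least 2 times their usual SD at a stage by the ratio of their mean absolute correlation among themselves to that with 1000 other IDs. It was compared, one-sided, with 100 random reassignments of residual libraries to stages. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used for these steps, and Matplotlib 3.10.9 for the plots.

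The tests, the grouping, the alternatives and the rule for naming IDs were chosen before the data were examined. The rule took the largest fold changes among called IDs with a gene name, a mean of at least 10 TPM in the higher class and no overlap between the classes, and allowed 2 rising and 2 falling IDs in all where no names were at hand. It did not say which comparison these should come from, and storage against fibrous roots was taken after the data were seen. The alternatives were other pseudocounts, other filters, median-of-ratios scaling, quantile normalization, library weights, a block for the replicate number, no fold threshold, a fit to the compared groups alone, linear diameter, a rank distance, a higher SD ratio and the removal of each library. Added after the data were seen were the count of IDs called under all 3 scalings (TPM as deposited, median-of-ratios and quantile), the stage profiles of those IDs, the counts of 8-fold changes under other pseudocounts, the test of departure from a straight line in log2 diameter, the fits without S4 replicate 1 in the shared spread, and the tests of the closing part.

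The steps were tested on simulated data. With no change simulated, 0 IDs were called in each of the 9 comparisons. Changed IDs were placed among 75757, with 67 at a log2 fold of 1.5, 67 at 2 and 66 at 3. They were drawn only from IDs with a mean log2(TPM + 1) above 2, and the noise was normal and independent between IDs. Recovery among lower IDs was therefore not measured. The storage and fibrous contrast recovered 79.1%, 97.0% and 97.0% of them with 10 false calls, and the S10 and S8 contrast recovered 53.7%, 79.1% and 90.9% with 9 false calls. For the network index, 2000 IDs were made to move together at S14 with 6 times their SD. The index was highest at S14 in 8 of 8 simulations, but its p fell under 0.05 in 5 of 8, so the index can miss an effect of that size. All 28 columns were used. No 2 columns were identical, and the correlation between libraries of the same stage ran from 0.801 to 0.932.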

Results

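Root transcriptomes of sweet potato were compared over 7 stages of thickening, from fibrous roots of 1.5 mm to storage roots of 25 mm, with 4 libraries per stage. The title of the series names root tuberization, the change of a thin root into a storage root, as its subject. Values are TPM as deposited. Sequencing depth was unknown, and the spread between replicates was the only measure of error.

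The main axis of variation ran from thin to thick roots, but did not order every stage, as S4 and S8 overlapped and so did S14 and S16. The first principal component held 41.5% of the variance and its stage means ran from -176 at S4 and -169 at S8, through -89.4 at S10 and 1.42 at S12, to 114 at S14, 109 at S16 and 209.8 at S20, with SDs between 9.62 and 39.4 (n = 4 each). The second component held 9.71% and set the pencil roots (-78.7 ± 16.9, SD, n = 8) apart from S4 (52.8 ± 37.8, SD, n = 4), S8 (57.2 ± 25.2) and S20 (91.8 ± 43.4), with S14 (-38.6 ± 14.5) and S16 (-5.81 ± 30.5) between them, so the thickest storage roots lay on the side of the fibrous roots. The number of IDs at 1 TPM or more was 50817 ± 2321 (SD, n = 8) in fibrous, 54908 ± 2005 (SD, n = 8) in pencil and 59387 ± 1038 (SD, n = 12) in storage roots, and the highest fibrous library (53493) lay below the lowest storage library (57957). The 1000 most abundant IDs of each library took 43.1% ± 5.01 (SD, n = 8) of the TPM in fibrous roots, against 35.9% ± 2.01 (SD, n = 8) in pencil and 34.7% ± 3.32 (SD, n = 12) in storage roots.

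**Figure D1:**
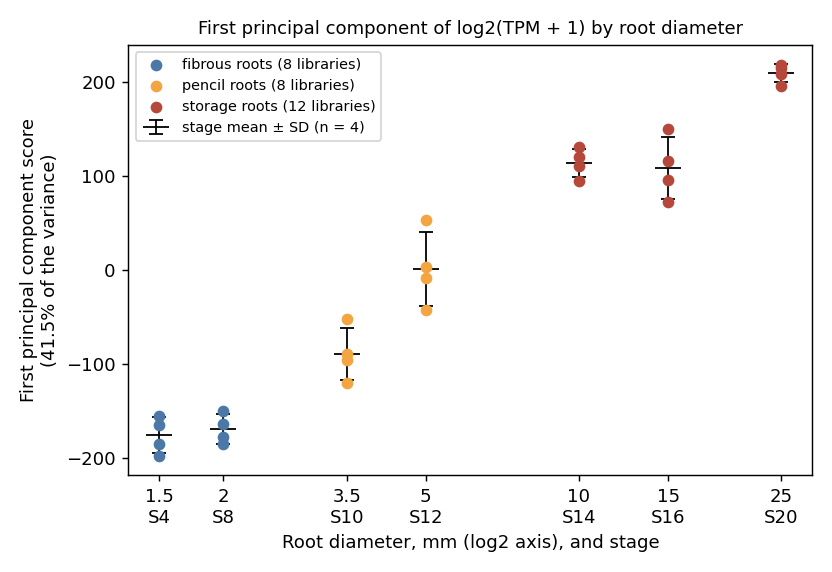
Score of each library on the first principal component of log2(TPM + 1), against root diameter in mm on a log2 axis, with points coloured by root class and black bars for the stage mean ± SD (n = 4). Scores of fibrous libraries lie between -198 and -150, and those of storage libraries between 73.0 and 218.

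Storage and fibrous roots were compared to describe the whole change. It was broad. Of 75757 IDs tested, 24793 were called (limma), 17478 higher and 7315 lower in storage roots, and the median log2 fold was 1.41 among the higher and -1.71 among the lower. The count was 9117 with a pseudocount of 5, 5266 higher and 3851 lower, and 48619 with no fold threshold. Changes of 8-fold or more (log2 of 3) were called for 583 higher and 1071 lower IDs, and which direction was more frequent depended on the pseudocount, with 3860 higher and 2700 lower at 0.1 and 116 and 393 at 5. The storage and fibrous libraries did not overlap for 10676 IDs that were higher and 3021 that were lower, where chance gives about 1.2 IDs (12 libraries against 8). Here and below, counts without overlap come from TPM as deposited. They were not computed under the other scalings, and their split by direction may depend on them.

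The balance of the directions depended on the scaling. The median log2 fold of all IDs was 0.45 in the deposited TPM, 0.10 after median-of-ratios scaling and 0.11 after quantile normalization. With median-of-ratios scaling the split was 9418 higher and 11088 lower, and with quantile normalization 9723 and 10365. Relative to the median fold of the deposited TPM it was 8182 and 10867. Here and below, that count moves the fold threshold by the median and keeps the adjusted p of the unshifted test, so it is not a separate test. Under all 3 scalings 8307 IDs were called higher and 7268 lower, which was 47.5% of the higher and 99.4% of the lower calls. Both rescalings lowered the median fold, which removes higher calls and keeps lower ones, so these shares do not compare how robust the directions are. No ID was called in opposite directions. That would need a fold to pass the threshold on both sides, a far larger shift than between these medians, so it was close to fixed in advance. Direction also went with level in this comparison. Of the called IDs with a mean of 1 to 5 TPM 77.1% were higher in storage roots, against 64.0% at 10 to 50 TPM and 39.6% at 100 TPM or more, where 704 of 1343 were called. The trend did not extend to the 1006 called IDs with a mean under 1 TPM, of which 55.6% were higher.

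**Figure D2:**
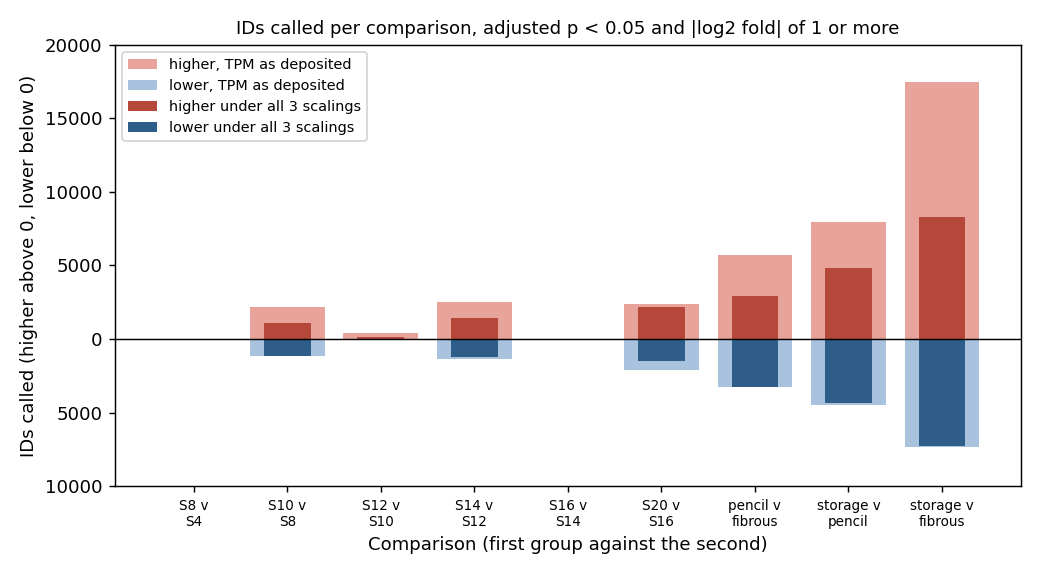
Number of IDs called in each comparison of the first group against the second, with higher IDs above 0 and lower IDs below 0. Pale bars use TPM as deposited, and narrow dark bars count IDs called in that direction under all 3 scalings. For storage against fibrous roots the bars stand at 17478 and 8307 above 0, and at 7315 and 7268 below it.

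The rule fixed for naming gave 4 IDs with large changes and no overlap between fibrous and storage libraries, none with a gene name here. G24701_TU40520 rose from 9.13 ± 11.4 TPM (SD, n = 8) in fibrous roots and 19.2 ± 13.6 (SD, n = 8) in pencil roots to 1777 ± 2453 (SD, n = 12) in storage roots, a log2 fold of 7.21 (SE 0.46, limma adjusted p = 3.78e-12). Its S20 libraries alone spanned 862 to 8153 TPM. MSTRG.435 was listed at 0 in all 8 fibrous libraries and held 2732 ± 1434 TPM (SD, n = 12) in storage roots, so no fold is given. The sum of MSTRG.435 and the next ID in the numbering was 4141 ± 2986 TPM (SD, n = 8) in fibrous and 3622 ± 1968 (SD, n = 12) in storage roots. MSTRG.17654 fell by 7.21 on the log2 scale (SE 0.41, limma adjusted p = 5.07e-13), from 952 ± 167 TPM (SD, n = 8) to 7.95 ± 7.80 (SD, n = 12), with pencil roots at 166 ± 127 (SD, n = 8). MSTRG.63597 fell from 364 ± 138 TPM (SD, n = 8) to 1.73 ± 2.47 (SD, n = 12) (limma adjusted p = 8.66e-08). It was listed at 0 in 5 of 12 storage libraries, so the size of its fall depended on the pseudocount, with a log2 fold of -9.17 at 0.1, -7.40 at 1 and -5.74 at 5. Its sum with the next ID was 482 ± 161 TPM (SD, n = 8) in fibrous and 16.6 ± 20.8 (SD, n = 12) in storage roots. All 4 kept their direction and their call under each alternative run, which the choice of large folds without overlap made likely in advance.

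Few IDs met a strict rule for absence in every library of 1 class and presence in every library of another. With depth unknown, a value of 0 need not mean absence. There were 8 IDs listed at 0 in every fibrous library with at least 1 TPM in every storage library, and 11 IDs with the reverse pattern. The 8 include MSTRG.435, whose zeros may reflect the assignment of reads, as the closing part describes. There were 0 IDs with at least 1 TPM in every pencil library and 0 in all others.

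Pencil roots differed from fibrous roots in 8964 called IDs (limma), 5717 higher and 3247 lower in pencil roots. The median log2 fold of all IDs was 0.22. The split was 3038 higher and 5821 lower with median-of-ratios scaling, 3372 and 4671 with quantile normalization, and 3411 and 4554 relative to the median. Under all 3 scalings 2952 IDs were higher and 3225 lower. By level the share of higher calls showed no steady trend, with 58.2% at a mean of 1 to 5 TPM, 68.4% at 10 to 50 TPM, 54.4% at 100 TPM or more and 19.5% under 1 TPM. The count of calls was 15949 with a pseudocount of 0.1 and 3048 with a pseudocount of 5. MSTRG.17654 fell by 3.08 in this step (SE 0.45, limma adjusted p = 1.33e-05) and MSTRG.63597 fell to 73.1 ± 106 TPM (SD, n = 8; limma adjusted p = 0.00109). In TPM as deposited, the only scaling for which this was computed, the libraries of the 2 classes did not overlap for 4252 higher and 976 lower IDs. Chance gives about 11.8, and the split by direction may depend on the scaling.

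Storage roots differed from pencil roots in 12368 called IDs (limma), 7922 higher and 4446 lower in storage roots. The median log2 fold of all IDs was 0.17. The split was 5515 higher and 5446 lower with median-of-ratios scaling, 5341 and 5495 with quantile normalization, and 5454 and 5654 relative to the median. Under all 3 scalings 4860 IDs were higher and 4362 lower. G24701_TU40520 rose by 5.71 in this step (SE 0.46, limma adjusted p = 1.36e-09), after 1.50 (SE 0.51, limma adjusted p = 0.0233) between fibrous and pencil roots, and MSTRG.17654 fell by 4.13 (SE 0.41, limma adjusted p = 2.17e-08). In TPM as deposited, the only scaling for which this was computed, the libraries of the 2 classes did not overlap for 2892 higher and 807 lower IDs. Chance gives about 1.2, and the split by direction may depend on the scaling. Of the called IDs with a mean of 1 to 5 TPM 81.0% were higher in storage roots, against 45.9% of those at 10 to 50 TPM and 17.8% of those at 100 TPM or more. The count of calls was 20695 with a pseudocount of 0.1 and 3906 with a pseudocount of 5, of which 1784 were higher and 2122 lower.

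The differences of pencil from fibrous roots and of storage from pencil roots, called steps here, were compared ID by ID. They are differences between classes of roots, not changes followed in the same root. There were 1155 IDs lower in both steps, where independent lists of these sizes share 191, and 789 higher in both, where independent lists share 598. There were 493 IDs higher and then lower, against 336, and 125 lower and then higher, against 340. Independent lists treat every ID as equally likely to be called, which did not hold. The called share was 1.41% under a mean of 1 TPM and 27.0% at 100 TPM or more for pencil against fibrous roots. For storage against pencil roots it was 2.18% and 38.6%. This shared dependence on level can raise overlaps, so the expected numbers are no chance level. The steps also share the pencil libraries, which pushes IDs towards opposite directions. With different pencil libraries in each step the counts were 1003 (153 from independent lists), 771 (472), 320 (275) and 55 (262). Simulated data with no change gave 0 calls in each step, so they hold no chance level for these overlaps.

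Neighbouring stages were compared to locate when expression changed. Few differences were detected between the thinnest roots, S4 and S8, with 1 ID called (limma) and 3034 IDs at an unadjusted p under 0.05. With no change, 5% of the 75757 IDs tested would fall there on average, which is more than 3034. The noise-corrected root mean square log2 change was 0.00, and at most 0.02 when any library was left out. The count was 10, 0, 7 and 10 without S4 replicate 1, 2, 4 and 5, and 4, 2 and 3 without S8 replicate 3, 4 and 5.

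The largest counts of calls came in 3 later steps. Between S8 and S10 3320 IDs were called (limma), 2175 higher and 1145 lower at S10, between S12 and S14 3880 were called, 2554 higher and 1326 lower at S14, and between S16 and S20 4491 were called, 2398 higher and 2093 lower at S20. The root mean square log2 change was 0.48, 0.50 and 0.52 in turn. Under all 3 scalings the IDs called higher and lower were 1125 and 1115 at S10, 1458 and 1201 at S14, and 2184 and 1455 at S20. With median-of-ratios scaling the splits were 1168 and 2547, 1562 and 1427, and 2534 and 1465, and with quantile normalization 1252 and 1577, 1761 and 1631, and 2558 and 2113. Lower calls were the more frequent at S20 with a pseudocount of 0.1 (1405 higher, 2801 lower), a pseudocount of 5 (823, 899) and a filter of 5 TPM (1371, 2072), and at S14 with a pseudocount of 5 (679, 731). Without S8 replicate 2 the S10 count was 2061, and without S12 replicate 2 or S14 replicate 3 the S14 count was 2186 or 2287.

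The steps within the pencil and the early storage roots gave fewer calls, and their counts moved strongly, up or down, when single libraries were left out. Between S10 and S12 512 IDs were called (limma), 446 higher and 66 lower at S12, and the splits were 208 and 86 with median-of-ratios scaling and 165 and 75 with quantile normalization. The count was 157, 1314 and 105 without S10 replicate 1, 2 and 3, and 130 without S12 replicate 4, and 9 in a fit to these stages alone. Between S14 and S16 101 IDs were called (limma), 34 higher and 67 lower at S16, with 9 and 31 after median-of-ratios scaling. The count was 10, 19, 1335 and 24 without S14 replicate 2, 3, 4 and 5, and 570, 52 and 11 without S16 replicate 1, 3 and 4. The root mean square log2 change was 0.29 and 0.30 in these steps, and its ranges on leaving out 1 library, 0.20 to 0.37 and 0.24 to 0.40, lay below those of the 3 larger steps, of which the lowest value was 0.44. The difference between steps was not tested. Per doubling of root diameter the change was 0.60 from S8 to S10, 0.57 from S10 to S12, 0.50 from S12 to S14, 0.52 from S14 to S16 and 0.71 from S16 to S20.

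Most IDs depended on stage. The limma F test found 46920 IDs (61.9% of those tested), and the slope on log2 diameter was past the threshold for 46711, of which 34110 rose and 12601 fell. The split of the slopes was 23048 and 19417 with median-of-ratios scaling and 23066 and 18844 with quantile normalization. Slopes of at least 0.5 per doubling of diameter were found for 6160 rising and 4021 falling IDs. A departure from the straight line, tested with limma, was found for 13323 IDs (17.6%), and 37611 IDs had a slope and no departure past the threshold. Of the 46920 IDs, 38.3% were highest at S20, 14.8% at S14 and 6.65% at S10, while 34.0% were lowest at S4, 23.2% at S8 and 22.4% at S20. These shares come from TPM as deposited, in which the median ID was higher in storage than in fibrous roots. They were not computed under the other scalings and may depend on them.

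The IDs that differed between storage and fibrous roots under all 3 scalings stood, by their medians, between their fibrous and storage levels in pencil roots. By definition the fibrous mean was 0% of the change and the storage mean 100%. The 8307 higher IDs had a median of 25.3% at S10, 56.9% at S12, 90.6% at S14, 93.6% at S16 and 116% at S20. The 7268 lower IDs had medians of 33.8%, 61.9%, 95.4%, 87.0% and 119%. The quartiles were wide, from 7.37% to 46.1% at S10 for the higher IDs.

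**Figure D3:**
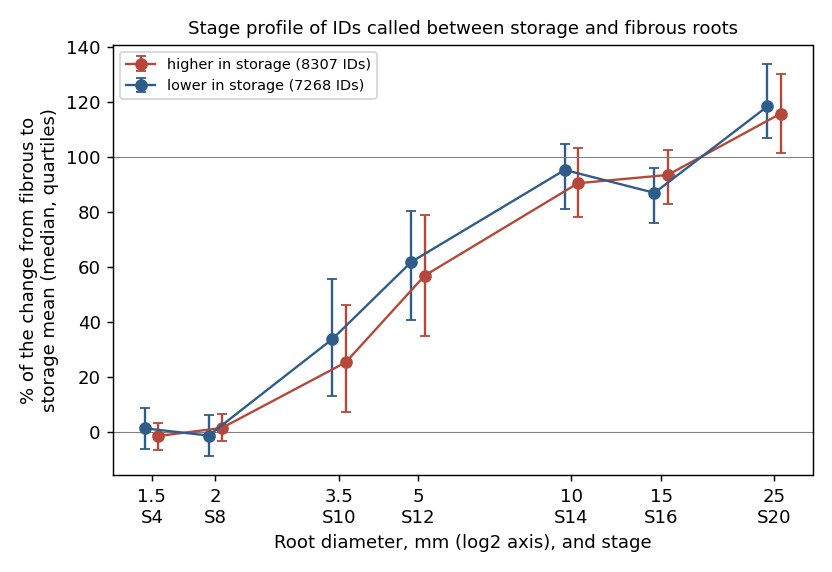
Stage means of IDs called between storage and fibrous roots under all 3 scalings, as a percentage of each ID's change from the fibrous to the storage mean, against root diameter in mm on a log2 axis. Points are medians over 8307 higher and 7268 lower IDs, bars are quartiles over IDs, both sets are drawn slightly apart along the axis, and the medians at S12 are 56.9% and 61.9%.

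The title of the series names a dynamic network biomarker analysis, which looks for a stage at which replicates fluctuate more. That method was not repeated here, and simpler measures were computed from TPM as deposited. In the replicate spread no stage passed the adjusted threshold. The same held for the network index, but there a single stage could not have passed, so it decides nothing. The mean distance of libraries from their stage mean was 0.581 ± 0.116 at S4, 0.485 ± 0.0212 at S8, 0.465 ± 0.0773 at S10, 0.502 ± 0.0461 at S12, 0.499 ± 0.0379 at S14, 0.523 ± 0.0235 at S16 and 0.506 ± 0.0936 at S20 (SD, n = 4 each). S4 exceeded the other libraries by 0.0847 (exact permutation p = 0.0326, adjusted 0.228), and 1 library, S4 replicate 1 at 0.752, held most of this. Without it the difference was -0.00800. The S4 difference passed the threshold with median-of-ratios scaling (exact permutation test, adjusted p = 0.00752), with the rank distance (0.0465), without S4 replicate 4 (0.0215) and without S4 replicate 5 (0.0168), and its adjusted p ran from 0.00752 to 0.879 over the alternatives. The exact permutation adjusted p of the other stages ran from 0.630 to 0.905.

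The network index was 1.08 at S4, 0.934 at S8, 1.10 at S10, 1.00 at S12, 1.00 at S14, 0.998 at S16 and 1.12 at S20, over 2877 to 13394 IDs per stage. The level and the order of the index depended on the settings. It ran from 1.55 to 2.01 with a pseudocount of 0.1, highest at S14, and from 1.19 to 1.54 with an SD ratio of 3, highest at S4. The medians under random reassignment lay between 1.02 and 1.05. At S4 the 13394 IDs exceeded the median of 3286 under reassignment (permutation p = 0.0198, not adjusted over the 7 stages). With 1 S4 library left out in turn, the S4 index ran from 0.892, without replicate 1, to 1.19. The number of IDs without replicate 1 is not given here, so that library alone may account for it. The permutation p of the index was lowest at S20 (0.238, adjusted 0.785), and the adjusted p was 0.785 or 0.832 at every stage. With 100 reassignments and 7 stages, a single stage could not have passed the adjusted threshold, and a correlation from 4 libraries is imprecise.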

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

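The tests of the scaling, of the level of expression and of the sum of neighbouring IDs, and the counts of other splits of the libraries, were written down after their results were seen. Gaps between a library and the other libraries of its stage were searched in 11 measures and 75 groups of 4 libraries. Of these gaps, 8 passed Dixon's criterion, and chance passes about 1 in 20 groups, here 3.75. The 2 numbers do not test for an excess, since 4 of the gaps are those of a set of IDs chosen for its differences within stages and 1 is a value of 0.17 TPM among zeros.

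A set of 13 IDs was near 0 in most libraries and high in single ones. These IDs were found among 109 IDs that reached 500 TPM and had a within-stage SD of at least 1 on the log2 scale, by a within-stage correlation above 0.9 with another member, and sets of at least 10 IDs were kept. Their mean correlation was 0.945, and 100 shuffles within stages gave no set larger than 2. Together they took 0.00141% ± 0.000617 of the TPM (SD, n = 8) in fibrous roots. In S12 replicate 4 the share was 1.02%, far from the other S12 libraries at 0.00114% to 0.00641% (gap 0.995 of the range). In S14 replicate 5 it was 2.01% against 0.00484% to 0.113% (gap 0.946), and in S16 replicate 1 it was 0.320% against 0.00425% to 0.0228% (gap 0.941). The S20 libraries held 5.92%, 0.958%, 0.137% and 3.30%. In S8 replicate 2 the share was the lowest of its stage, 0.000780% against 0.00154% to 0.00159% (gap 0.938).

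Carry-over of RNA or reads from S20 libraries was tested as an explanation. In S12 replicate 4 the set stood at 39.3% of its S20 mean above the other S12 libraries, while 150 other IDs that mark S20 stood at a median of 1.33% (quartiles -0.0967% and 6.28%), with 12.7% of them at 20% or more. In S14 replicate 5 the set stood at 76.4% and 32 such IDs at a median of 0.422%, with 6.25% of them at 20% or more. Carry-over needs these IDs to rise together with the set, so the medians argue against it in both libraries, and the few IDs that did rise are not explained. A response of single roots may be a biological explanation and, like a different mix of cell types in the sampled section, was not tested, since the labels describe no difference between replicates and no ID had a gene name.

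The 100 most abundant IDs took 23.8% of the TPM in S14 replicate 5, against 14.6% to 15.5% in the other S14 libraries (gap 0.907). MSTRG.63597 held 283 TPM in S12 replicate 2, against 0.02 to 27.7 in the other S12 libraries (gap 0.902), and 7.86 TPM in S14 replicate 3, against 0 to 0.40 (gap 0.949). MSTRG.435 was at 0.17 TPM in S10 replicate 3 and at 0 in the other S10 libraries (gap 1 of the range).

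MSTRG.435 had the largest rise between fibrous and storage roots among the IDs the naming rule allowed, and the ID that follows it in the numbering, chosen after its values were seen, ran the other way. That ID held 4141 ± 2986 TPM (SD, n = 8) in fibrous roots and was at 0 in 6 of 12 storage libraries, while MSTRG.435 was at 0 in 8 of 8 fibrous libraries. In storage roots it held 889 ± 1601 TPM (SD, n = 12), and the log2 difference between storage and fibrous roots was 0.0220 for the sum of both IDs (SE 0.43, exact permutation p = 0.959 over 125970 choices, 8 and 12 libraries). Assignment of the same reads now to 1 ID and now to the other may account for the rise, and a real change from 1 copy or transcript form to another stays open, since no sequences were used here.

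More IDs were called higher than lower in storage than in fibrous roots, 70.5% of the calls. With the 1000 most abundant IDs removed and TPM rescaled, the share was 66.6%, which argues against a few abundant IDs as the whole cause. With median-of-ratios scaling it was 45.9%, but that scaling moves the median of all IDs towards 0 by construction, so a scale factor per library and a general change cannot be told apart. Weaker detection of rare transcripts in fibrous roots was left undecided too, since the share was 42.3% among IDs with a mean of at least 50 TPM but that test was chosen from a trend with level already seen. A larger variety of transcripts in storage roots would have the same effect and stays open, untested.

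The real grouping gave more calls than every other split drawn for most comparisons. That was so in 1 of 35 splits for S10 against S8 (3320, highest other 33), S14 against S12 (3880, highest other 1919) and S20 against S16 (4491, highest other 253). It was so in 1 of 100 for pencil against fibrous (8964, highest other 2946), storage against pencil (12368, highest other 186), storage against fibrous roots (24793, highest other 11782), the F test (46920, highest other 245) and the slope (46711, highest other 1). For these, no other split drawn reached the real count, which argues against chance but does not exclude it. Each share is the smallest its number of splits can give, and none was adjusted over the results. For S12 against S10 the real 512 was also highest, 1 of 35, but the next split gave 483. The count fell to 105 without S10 replicate 3, 157 without S10 replicate 1 and 130 without S12 replicate 4. Chance was not excluded there, and the case against it was weaker. For S8 against S4, 25 of 35 splits gave at least as many calls as the real 1, with up to 156, and for S16 against S14 2 of 35 gave at least 101, with up to 1156, so chance was not excluded for either. Splits with several times the real count may reflect a structure among these libraries other than stage, or single libraries that stand apart, since the S16 count was 1335 without S14 replicate 4, and neither was tested.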

How the results depend on the processing

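No pairing of the libraries by replicate number was detected, though a weak pairing would not show in these measures. Of 66 pairs of libraries from different stages with the same number, 8 had residuals correlated above 0.1. The mean correlation of the 66 was 9.69e-05, against -5.06e-05 for pairs with different numbers. The best partner of 6 of 28 libraries shared its number. With a replicate block the counts were 0 (S8 and S4), 231 (S12 and S10) and 40 (S16 and S14), and with a block on the title numbers 2 (S8 and S4) and 52 (S16 and S14), and the other counts stayed within 1.5 times.

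Of 367 values under alternatives, for 18 results, 300 kept their side of the threshold or stayed within 1.5 times of the reported count. These do not speak for direction. The majority of higher or lower calls turned in 19 of 247 values, for 9 of 10 results, and the difference in spread, past the threshold at no stage as reported, changed sign in 13 of 83 values, for 6 of 7 stages. The network index is left out of these numbers, since a single stage could not pass its threshold, and its values ran from 1.55 to 2.01 with pseudocount 0.1 and from 1.19 to 1.54 with an SD ratio of 3. For those that moved, the cause was not tested, apart from settings that test fewer IDs or fewer libraries. Pseudocount 0.1 gave 4 (S8 and S4), 8 (S16 and S14), 15949 (pencil and fibrous) and 20695 (storage and pencil). Pseudocount 5 gave 0 (S8 and S4), 1370 (S10 and S8), 158 (S12 and S10), 1410 (S14 and S12), 1722 (S20 and S16), 3048 (pencil and fibrous), 3906 (storage and pencil) and 9117 (storage and fibrous). A filter of 5 TPM, which tests fewer IDs, gave 0 (S8 and S4), 0 (S16 and S14), 30772 (F test) and 29062 (slope). Median-of-ratios scaling gave 2 (S8 and S4), 294 (S12 and S10) and 40 (S16 and S14), and quantile normalization 2 (S8 and S4) and 240 (S12 and S10). Library weights gave 2 (S8 and S4), 5220 (S10 and S8), 2160 (S12 and S10), 5978 (S14 and S12) and 1038 (S16 and S14). No fold threshold gave 6132 (S10 and S8), 6051 (S14 and S12), 7132 (S20 and S16), 26402 (pencil and fibrous), 32903 (storage and pencil) and 48619 (storage and fibrous). A fit to the compared groups alone gave 0 (S8 and S4), 9 (S12 and S10), 1894 (S14 and S12), 3 (S16 and S14) and 2281 (S20 and S16).

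Without 1 library in turn the counts ran from 0 to 10 (S8 and S4), 2061 to 3431 (S10 and S8), 105 to 1314 (S12 and S10), 2186 to 4823 (S14 and S12), 10 to 1335 (S16 and S14), 3184 to 4992 (S20 and S16), 8314 to 9780 (pencil and fibrous), 11752 to 13229 (storage and pencil), 23946 to 25473 (storage and fibrous), 44265 to 47775 (F test) and 45368 to 46856 (slope). Beside the counts of 0, limma on the deposited values gave 3034 (S8 and S4) and 8543 (S16 and S14) IDs at an unadjusted p under 0.05. With no change, 5% of the 75757 IDs tested would fall there on average, which is more than 3034 and fewer than 8543. The 4 named IDs kept their direction and their call throughout, as was likely from the way they were chosen. The S4 spread difference ran from -0.00800 to 0.130 (exact permutation test), and it passed with median-of-ratios scaling (0.135) and with the rank distance (0.0426, on its own scale). Gene list tests, IbNAC083 and their alternatives were not run, since no ID was matched to a name. Depth limits all of this in an unknown way.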

Other observations

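The patterns below were found and tested on the same libraries, and all of their tests were chosen after the data were seen.

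Another 2 sets of IDs moved together between replicates. A set of 15 IDs (mean within-stage correlation 0.845) took 0.832% ± 0.245 of the TPM (SD, n = 8) in fibrous, 0.288% ± 0.205 (SD, n = 8) in pencil and 0.0659% ± 0.0484 (SD, n = 12) in storage roots. In pencil roots its share ran from 0.0405% in S12 replicate 4 to 0.592% in S10 replicate 3. A set of 11 IDs (mean correlation 0.888) took 0.220% ± 0.0791 (SD, n = 8), 0.149% ± 0.103 (SD, n = 8) and 0.226% ± 0.286 (SD, n = 12) in turn, and ran from 0.0145% in S20 replicate 1 to 1.09% in S20 replicate 3.

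IDs of the MSTRG kind were 24.6% of those tested, 17.0% of those called higher in storage than in fibrous roots (odds ratio 0.561, Fisher's exact p = 1.41e-161) and 27.4% of those called lower (odds ratio 1.18, Fisher's exact p = 2.98e-09). Among lower calls neither step showed this, with an odds ratio of 1.06 for pencil against fibrous roots (Fisher's exact p = 0.150) and 1.01 for storage against pencil roots (Fisher's exact p = 0.872). These p-values treat IDs as independent, which they are not.

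Neighbouring MSTRG IDs that replaced each other were searched for in 13202 pairs with consecutive numbers. A pair counted where, among libraries with a sum of at least 20 TPM, each ID fell under 1% of the sum in at least 3. There were 9 such pairs, and 0 at each of 5 larger distances in the numbering. They include MSTRG.435 and MSTRG.63597. For MSTRG.63597 the log2 difference between storage and fibrous roots for the sum with the next ID was -5.49, so the sum fell too.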
